A study of Homo sapiens with 4 samples.

How the data were processed

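The data are gene-level RNA-seq values of 4 libraries from MHCC97H cells, 2 of wild-type cells (control) and 2 of cells with HNRNPM knocked down by a short hairpin RNA. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase, depleted of ribosomal RNA, made into libraries with a stranded kit that adds random molecular identifiers before amplification, and sequenced paired-end on an Illumina NovaSeq. Per the submitters' processing notes, Trimmomatic 0.36, featureCounts, Subread 1.5.1, edgeR 3.12.1 and StringTie 1.3.2 were used. The aligner, the handling of the molecular identifiers and the strand setting of the counting are not given in the sources used here. The notes name the mouse build mm9, but the coordinates of the deposited tables match human GRCh38: of 26367 gene names found once in the GENCODE annotation used here, 99.9% lay on the same chromosome and 93.7% had the same start and end. All coordinates are those of the files.

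Each deposited table held 1 RPKM value per gene name for 39306 names, computed by the authors from reads over annotated exons and scaled to the total of assigned reads. RPKM times exon length in kilobases summed to the same round total in each library, and 100% of the values were whole multiples of the value of 1 read, within 0.01 of a read. The recovered totals were 18317579 and 19659106 reads in the controls and 12708165 and 11498663 reads in the knockdown libraries, so the knockdown libraries are shallower. Loci with one name on several chromosomes are merged in these tables (128 names). The deposited values are RPKM and not counts, and the count model planned before the data were examined was replaced by limma on log values. A classic exact test and a second count-based tool were not run either. The recovered reads would have allowed such fits, and only limma-voom was run on them. No exon usage test was run, since the tables give single values per gene.

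RPKM values were divided by TMM factors (trimming 30% of log ratios and 5% of mean levels, computed on the recovered reads; 0.984 and 0.972 for the controls, 1.03 and 1.02 for the knockdown libraries) and tested as log2(RPKM + 0.1) with limma 3.58.1 in R 4.3.3, with a spread moderated along expression, group as the only term and Benjamini-Hochberg adjustment. The pseudocount of 0.1 was chosen after the files had been seen, so 1 and 0.01 were tried as well. Fold changes are on this scale, which understates changes of genes at low levels. Genes were tested if at least 2 libraries reached the equivalent of 10 reads in a library of median depth and the total was at least 15 reads, which left 20221. The threshold was an adjusted p of 0.05. The fit had 2 residual and 3.56 prior degrees of freedom, and with 2 libraries against 2 an exact permutation test of 1 gene cannot go below p = 0.333, so every p-value leans on limma's pooled spread. On simulated data with 200 changed genes among 20092 tested, this procedure recovered 2.99%, 43.3% and 84.8% of genes changed by 0.5, 1 and 2 on the log2 scale, and 2.25% of its calls were unchanged genes. Limma-voom recovered 53.7%, 77.6% and 97.0%, with 3.80% of its calls unchanged genes. With more changed genes, as in these data, the adjusted threshold is less strict than in the simulation. Counting intervals cover sampling error only.

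The 41 gene lists were fixed before the data were examined, as were the comparisons, the main alternatives and the rule for named genes. Some genes are members of several lists, so the lists are not fully separate. Older symbols were matched through the RefSeq gene table. Lists were tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. An estimated correlation and the rotation test fry were alternatives. With an estimated correlation, camera's p-values rest on the 2 residual degrees of freedom and not on all genes. Such p-values can hardly be small with 4 libraries, so a list failing this alternative is not thereby shown to be unchanged. Tested on simulated lists, camera with the preset correlation called 5 of 5 shifted and 0 of 36 unshifted lists. The simulated lists were random genes that varied independently. They do not show how often the test calls unshifted lists of correlated genes, such as ribosomal protein genes (estimated correlation 0.78). Genes of each chromosome with at least 20 tested genes were tested in the same way, leaving out the Y chromosome. The named genes are HNRNPM, TRIM7 and the genes antisense to it, the 15 largest increases and 15 largest decreases among called genes with a mean CPM of at least 5, non-overlapping groups and a symbol that is not a clone name, and up to 4 members of each list with the smallest adjusted p. Where no member of a list passed, the 2 most abundant were to be named. Receptor targets named only in the closing section were chosen after values had been seen.

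The alternatives were median-of-ratios factors, total reads only, scaling without mitochondrial, histone and structural RNA genes, no filter, a stricter filter (a mean CPM of at least 1), limma-voom on the recovered reads, stricter thresholds, a block for the replicate number, and leaving out each library in turn, where the lone library of a group is assumed to vary like the other group. Chosen after seeing the data were the other pseudocounts, thinning all libraries to the depth of the shallowest, removal of the trend with exon length from every library, and robust moderation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.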

Results

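RNA sequencing of ribosomal RNA-depleted total RNA was used to compare 4 libraries of MHCC97H, an established human hepatocellular carcinoma cell line with high metastatic capacity. The 2 control libraries came from wild-type cells and the 2 knockdown libraries from cells carrying a short hairpin RNA against HNRNPM, which encodes heterogeneous nuclear ribonucleoprotein M, an RNA-binding protein and splicing regulator. The labels give each library as a replicate of its group without saying whether the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Gene-level values were in RPKM, reads per kilobase of exon scaled to the total of assigned reads. The assigned reads recovered from them were 18317579 and 19659106 for control replicates 1 and 2, and 12708165 and 11498663 for knockdown replicates 1 and 2. Log2 values of the 2 controls correlated across genes with r = 0.991 and those of the 2 knockdown libraries with r = 0.989, while pairs from different groups reached 0.968 to 0.969. The chi-square per gene against read sampling was 7.65 between the controls and 2.21 between the knockdown libraries. It grows with depth, so it does not rank the pairs by spread. The SD of log2 differences across genes was 0.294 between the controls and 0.310 between the knockdown libraries. Technical repeats can differ by more than read sampling too, and reads may not be independent molecules, so these values do not show that the replicates were separate cultures. All 4 were analysed as samples.

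The comparison of knockdown with control cells asks which genes differ after HNRNPM knockdown, and the series title names TRIM7, a member of the tripartite motif ubiquitin ligase family, and its antisense long non-coding RNA. HNRNPM (GRCh38 chromosome 19, positions 8444767 to 8489114, plus strand, measured over its annotated exons) fell from 51.5 ± 0.188 RPKM (SD, n = 2) in control cells to 21.1 ± 0.956 RPKM (SD, n = 2) in knockdown cells, which is 41.0% of the control level. Its log2 fold change was -1.35 ± 0.07 (SE; limma adjusted p = 0.00270), and the 95% confidence interval of the fold ran from 0.35 to 0.44. TRIM7 (chromosome 5, positions 181193924 to 181205293, minus strand) was measured at 0.887 ± 0.00877 RPKM in control and 0.953 ± 0.195 RPKM in knockdown cells (SD, n = 2 each), from 76 to 127 reads per library. Its difference was not distinguishable from 0 (log2 fold change 0.02 ± 0.19, limma adjusted p = 0.942), and the 95% interval of the fold, 0.726 to 1.42, leaves changes of that size open in either direction. Without knockdown replicate 2 the TRIM7 estimate was -0.17 on the log2 scale. Opposite to TRIM7 on the plus strand lies CTC-338M12.5 (positions 181191924 to 181194429), which shares 506 bp with the TRIM7 locus. CTC-338M12.6 (positions 181195496 to 181203103) lies within the locus. The labels do not say which of them is the named antisense RNA. CTC-338M12.5 was measured at 4.12 ± 0.206 RPKM in control and 2.67 ± 1.03 RPKM in knockdown cells, with a log2 fold change of -0.72 ± 0.26 that did not pass the threshold (limma adjusted p = 0.0976). It passed without knockdown replicate 2 (log2 fold change -1.12, limma adjusted p = 0.0144). CTC-338M12.6 had only 4 to 12 reads per library, and its log2 fold change of 0.64 ± 0.37 did not pass (limma adjusted p = 0.25). The strand setting of the counting is not given in the sources used here, so reads of TRIM7 and of these genes may not be separated where they overlap. HNRNPM likewise overlaps an antisense gene. The controls are given as wild type with no control hairpin named, and whether both knockdown libraries carry the same hairpin is not stated. Effects of hairpin delivery or of off-target silencing are thus not separated from loss of HNRNPM in any gene or list.

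**Figure D1:**
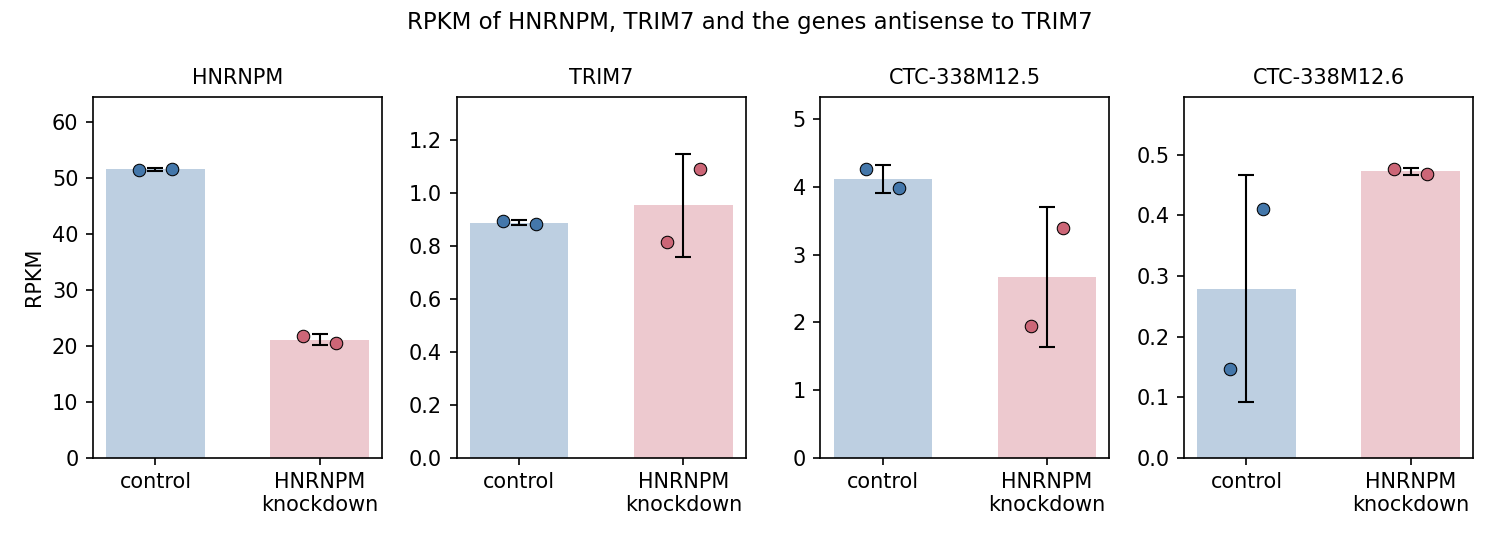
RPKM (vertical axes, each starting at 0) of HNRNPM, TRIM7 and the genes antisense to TRIM7 in control and HNRNPM knockdown cells. Points are the 2 libraries of a group, bars their mean and error bars 1 SD; HNRNPM was at 51.5 RPKM in control and 21.1 RPKM in knockdown cells, while the TRIM7 libraries of the knockdown group lie on both sides of the controls.

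Across the transcriptome, 5032 of 20221 tested genes differed between the groups (limma, adjusted p under 0.05), of which 2240 were higher and 2792 lower in knockdown cells. A log2 change of at least 1 was reached by 460 of the higher and 402 of the lower genes. With the values scaled only to total reads, as deposited, the split turned to 2783 higher and 2234 lower genes, or 55.5% higher in place of 44.5%. After removal of the trend with exon length it was 2545 higher and 2496 lower. The libraries of the groups did not overlap in 13674 tested genes (67.6%), against 33.3% by chance. The largest increase was in FOSB, an AP-1 subunit, from 0.343 ± 0.110 to 15.1 ± 1.11 RPKM (log2 fold change 5.06 ± 0.20). CYP1A1, a cytochrome P450 that metabolises aromatic hydrocarbons, followed with a log2 fold change of 4.03 ± 0.14, reaching 6.68 ± 0.149 RPKM. DUSP1, a MAP kinase phosphatase, rose from 4.05 ± 0.276 to 27.8 ± 1.79 RPKM, and FOS from 10.6 ± 0.369 to 64.5 ± 3.24 RPKM. Increases of 1.82 to 2.31 on the log2 scale were found in CST1 (cystatin SN), LYVE1 (a hyaluronan receptor), KRT7 (keratin 7), MAP7D2, APOA4 (an apolipoprotein), PDZK1IP1, IL32 and EGR1. KRT7 rose from 8.08 ± 1.91 to 40.7 ± 1.29 RPKM and APOA4 from 4.63 ± 0.0544 to 23.6 ± 0.635 RPKM. The largest decrease was in ADH1C, an alcohol dehydrogenase, from 19.2 ± 2.27 to 1.43 ± 0.227 RPKM (log2 fold change -3.72 ± 0.15). RNU1-28P, a U1 small nuclear RNA pseudogene that can share reads with its copies, and MIR3687-2, in the 5' external spacer of ribosomal RNA genes, had log2 fold changes of -3.21 and -3.01. ABCG1, a sterol exporter, fell from 2.33 ± 0.729 to 0.202 ± 0.00479 RPKM and SOST (sclerostin) to 1.52 ± 0.223 RPKM (log2 fold change -2.84). Lower levels were also found for the liver plasma proteins ALB (5.82 ± 0.658 against 1.76 ± 0.0207 RPKM) and AMBP (log2 fold change -1.84 ± 0.10), for the tight junction gene CLDN2, for SLC7A11 (the cystine transporter), and for COLCA1, CDH6, DPY19L1, TLR1, ERLIN1 and TSPAN8, all with log2 fold changes of -1.62 or lower. KRT7, IL32, COLCA1, CDH6, CLDN2, SLC7A11, TLR1 and ERLIN1 overlap exons of other genes, so their values may hold reads of a neighbour. Errors of RPKM values are SDs over the 2 libraries of each group and those of log2 fold changes are limma's SEs. Each named change passed limma's test with an adjusted p of 0.00156 to 0.00689.

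**Figure D2:**
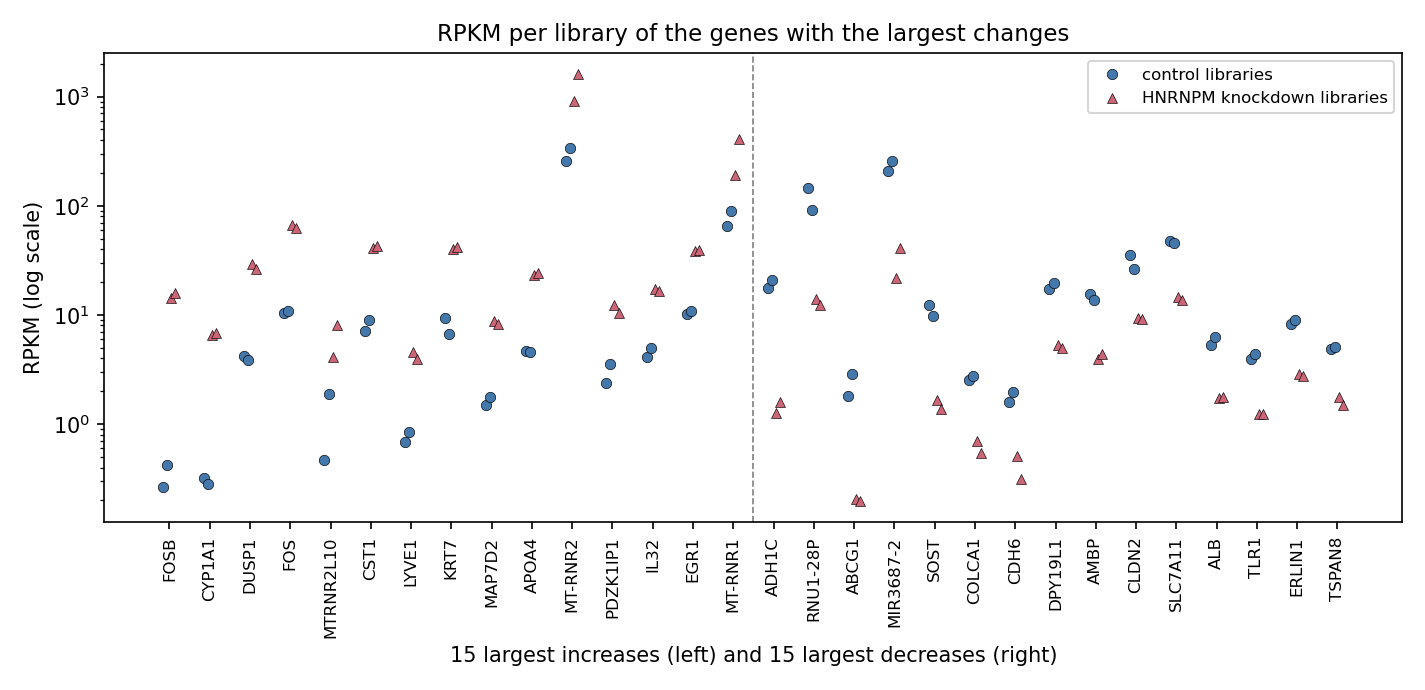
RPKM per library (vertical axis, log scale) of the 15 largest increases (left of the dashed line) and 15 largest decreases (right) after HNRNPM knockdown. Circles are the 2 control and triangles the 2 knockdown libraries. The points of the groups do not overlap in any of these genes, since the rule that chose them required this. FOSB spans 0.343 RPKM in control to 15.1 RPKM in knockdown cells on average.

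Immediate early genes, which respond within minutes to growth factors and stress, rose as a group. Of 25 tested members of this list, 23 were higher, 1 was lower and 1 was not called (24 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.99 (camera adjusted p = 3.91e-15, and adjusted p = 0.727 with an estimated correlation). Besides FOSB, DUSP1 and FOS, EGR1 rose from 10.5 ± 0.508 to 38.9 ± 0.871 RPKM (SD, n = 2) and JUN from 27.7 ± 1.27 to 65.7 ± 0.128 RPKM. Hypoxia targets rose too, with 19 of 26 members higher and 2 lower (21 and 2 adjusted over the list alone; median 0.77; camera adjusted p = 4.98e-10, and adjusted p = 0.755 with an estimated correlation). BNIP3L and BNIP3, which mark mitochondria for autophagy, had log2 fold changes of 1.40 ± 0.07 and 1.22 ± 0.08, DDIT4, an mTOR inhibitor, 1.23 ± 0.08 and NDRG1 1.21 ± 0.08. In the glycolysis list 11 of 19 genes were higher and 1 lower (12 and 1 adjusted over the list alone; median 0.35; camera adjusted p = 0.000203, and adjusted p = 0.727 with an estimated correlation), among them ALDOC (1.33 ± 0.08), ENO2 (1.04 ± 0.10), LDHA (0.68 ± 0.09) and PGK1 (0.58 ± 0.07). NF-kB targets and cytokines had 14 of 23 members higher and 2 lower (16 and 3 adjusted over the list alone; median 0.65; camera adjusted p = 0.000243, and adjusted p = 0.813 with an estimated correlation). The chemokine gene CCL20 rose from 0.842 ± 0.0411 to 5.81 ± 0.0679 RPKM and NFKBIZ by 1.67 ± 0.12 on the log2 scale. CSF1, a macrophage growth factor, fell from 37.1 ± 1.68 to 16.4 ± 0.189 RPKM. The rotation test fry, which asks only whether a list's genes moved one way, called immediate early genes and glycolysis (adjusted p = 0.0142 for both). With an estimated correlation the glycolysis list had an unadjusted camera p of 0.0539, against 3.46e-05 with the preset one. Its estimated correlation, 0.0104, was close to the preset 0.01, so this loss came mostly from the 2 residual degrees of freedom. Without knockdown replicate 1 and without knockdown replicate 2, the genes called higher numbered 15 and 15 for immediate early genes, 14 and 14 for hypoxia targets, 4 and 5 for glycolysis, and 10 and 11 for NF-kB targets. BNIP3L, DDIT4 and ALDOC overlap exons of other genes and are uncertain.

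Called genes of cytosolic ribosomal proteins and histones were higher, while mitochondrial transcripts moved in both directions. Of 54 cytosolic ribosomal protein genes 41 were higher and 0 lower (46 and 0 adjusted over the list alone), with a median log2 fold change of 0.43 (camera adjusted p = 4.32e-16, and adjusted p = 0.755 with an estimated correlation). RPS12 rose from 178 ± 13.8 to 306 ± 16.6 RPKM, RPL32 from 148 ± 15.1 to 251 ± 7.23 RPKM and RPS15 from 80.9 ± 0.608 to 130.2 ± 0.368 RPKM (SD, n = 2). RPL32 overlaps exons of other genes, and ribosomal protein genes have many processed copies, which makes single values uncertain. Their annotated exons are not all short, with 767 bp for RPS12, 2137 bp for RPS15 and 3720 bp for RPL32. Median fold changes fell slightly with exon length, from 0.03 in the shortest 10% of genes to -0.08 in the longest 10%. The direction of calls shifted more clearly. In the shortest 10% of genes 331 were called higher and 272 lower, and in the longest 10% 122 higher and 318 lower. Replication-dependent histone genes had 17 of 22 members higher and 0 lower (19 and 0 adjusted over the list alone; median 0.59; camera adjusted p = 8.90e-10, and adjusted p = 0.755 with an estimated correlation), among them HIST1H1A (0.91 ± 0.11) and HIST1H4E (0.89 ± 0.08). Without knockdown replicate 1 and without knockdown replicate 2, only 11 and 15 ribosomal protein genes and 8 and 8 histone genes were called, all higher. Histone genes took 0.155% and 0.129% of reads in the controls and 0.222% and 0.219% in the knockdown libraries. The mitochondrially encoded mRNAs were lower as a list (median log2 fold change -0.50, camera adjusted p = 0.00274, and adjusted p = 0.813 with an estimated correlation), although only 2 of 13 passed singly (2 adjusted over the list alone). These were MT-ND3 (-0.77 ± 0.11) and MT-CYB (-0.74 ± 0.14), and neither passed without either knockdown library (adjusted p between 0.0611 and 0.180). The count of lower mitochondrial mRNAs depended on the setting, with 12 by limma-voom, 10 with robust moderation, 6 without control replicate 1, 4 with the stricter filter and 0 without either knockdown library. The list as a whole did not pass without knockdown replicate 1 (camera adjusted p = 0.163). Their share of reads was 4.77% and 5.19% in the controls and 3.45% and 3.84% in the knockdown libraries. The mitochondrial ribosomal RNAs rose, MT-RNR2 from 298 ± 59.7 to 1255 ± 487 RPKM (limma adjusted p = 0.0104) and MT-RNR1 from 77.4 ± 17.8 to 298 ± 151 RPKM (limma adjusted p = 0.0230). MT-RNR1 did not pass without control replicate 1 or 2 (adjusted p = 0.0979 and 0.0624). MTRNR2L10, a nuclear gene copied from MT-RNR2 that can take its reads, rose by 2.41 ± 0.64 and did not pass without control replicate 1 (adjusted p = 0.0913) or knockdown replicate 2 (adjusted p = 0.10).

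The genes called in either cell cycle list were all lower, except for 1 G1/S gene that limma-voom called higher. In the G2/M list 24 of 30 genes were lower and 0 higher, also when adjusted over the list alone, with a median log2 fold change of -0.52 (camera adjusted p = 4.96e-10, and adjusted p = 0.727 with an estimated correlation). ASPM, a spindle pole protein, fell from 34.2 ± 1.76 to 13.7 ± 0.269 RPKM, CENPF from 45.2 ± 3.02 to 23.7 ± 0.420 RPKM, CCNB1 (cyclin B1) from 47.5 ± 0.818 to 28.9 ± 1.57 RPKM and MKI67, the proliferation marker, from 65.5 ± 4.01 to 42.4 ± 0.605 RPKM (SD, n = 2). The G1/S and DNA replication list had 12 of 33 genes lower and 0 higher (14 and 0 adjusted over the list alone; median -0.25; camera adjusted p = 0.000303, and adjusted p = 0.755 with an estimated correlation). POLE, the catalytic subunit of DNA polymerase epsilon, had a log2 fold change of -0.81 ± 0.11, and the helicase subunits MCM6 and MCM5 -0.52 ± 0.07 and -0.50 ± 0.07. Without knockdown replicate 1 and without knockdown replicate 2, 16 and 13 G2/M genes and 5 and 5 G1/S genes were called lower. The rotation test fry called G2/M (adjusted p = 0.0234).

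In lists of the stress response, NRF2 targets, lysosomes and fatty acid metabolism, more of the called genes were lower than higher. SLC7A11 is a member of both the stress response and the NRF2 list, so these are not fully separate results. The list of the unfolded protein and integrated stress response had 16 of 31 members lower and 4 higher (18 and 5 adjusted over the list alone; median -0.37; camera adjusted p = 0.00391, and adjusted p = 0.727 with an estimated correlation). SLC7A11 fell from 46.2 ± 1.49 to 14.2 ± 0.654 RPKM and its partner subunit SLC3A2 from 56.2 ± 1.39 to 25.5 ± 0.371 RPKM (SD, n = 2). In contrast PPP1R15A, a phosphatase subunit that ends the integrated stress response, rose from 29.1 ± 2.60 to 74.7 ± 1.56 RPKM. Of 25 NRF2 targets 14 were lower and 2 higher (18 and 2 adjusted over the list alone; median -0.36; camera adjusted p = 0.000136, and adjusted p = 0.755 with an estimated correlation). They include the transporters ABCC2 (101 ± 0.192 against 44.4 ± 0.174 RPKM) and ABCC1 (log2 fold change -0.90 ± 0.07). AKR1B10, an aldo-keto reductase, had a log2 fold change of -1.06 ± 0.13 and did not pass without either knockdown library (adjusted p = 0.0546 and 0.0554). The lysosome and autophagy list had 13 of 30 members lower and 4 higher (16 and 5 adjusted over the list alone; median -0.31; camera adjusted p = 0.0157, and adjusted p = 0.755 with an estimated correlation). GLA (alpha-galactosidase A) and CTSD (cathepsin D) had log2 fold changes of -0.82 ± 0.08 and -0.93 ± 0.09. In fatty acid synthesis and oxidation 8 of 27 genes were lower and 1 higher (10 and 2 adjusted over the list alone; median -0.18; camera adjusted p = 0.0212, and adjusted p = 0.813 with an estimated correlation). SREBF1, a transcription factor of lipid synthesis, fell from 27.3 ± 3.05 to 10.3 ± 0.418 RPKM and ACACA (acetyl-CoA carboxylase) from 16.6 ± 0.861 to 8.52 ± 0.0848 RPKM. PLIN2, a lipid droplet coat protein, rose from 10.7 ± 0.0815 to 26.0 ± 1.11 RPKM. Without knockdown replicate 1 and without knockdown replicate 2, the genes called lower numbered 9 and 7 for the stress response, 5 and 5 for NRF2 targets, 8 and 9 for lysosome genes, and 7 and 8 for fatty acid genes. SLC7A11, CTSD and SREBF1 overlap exons of other genes and are uncertain. Of these lists, fry called the stress response (adjusted p = 0.0142).

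**Figure D3:**
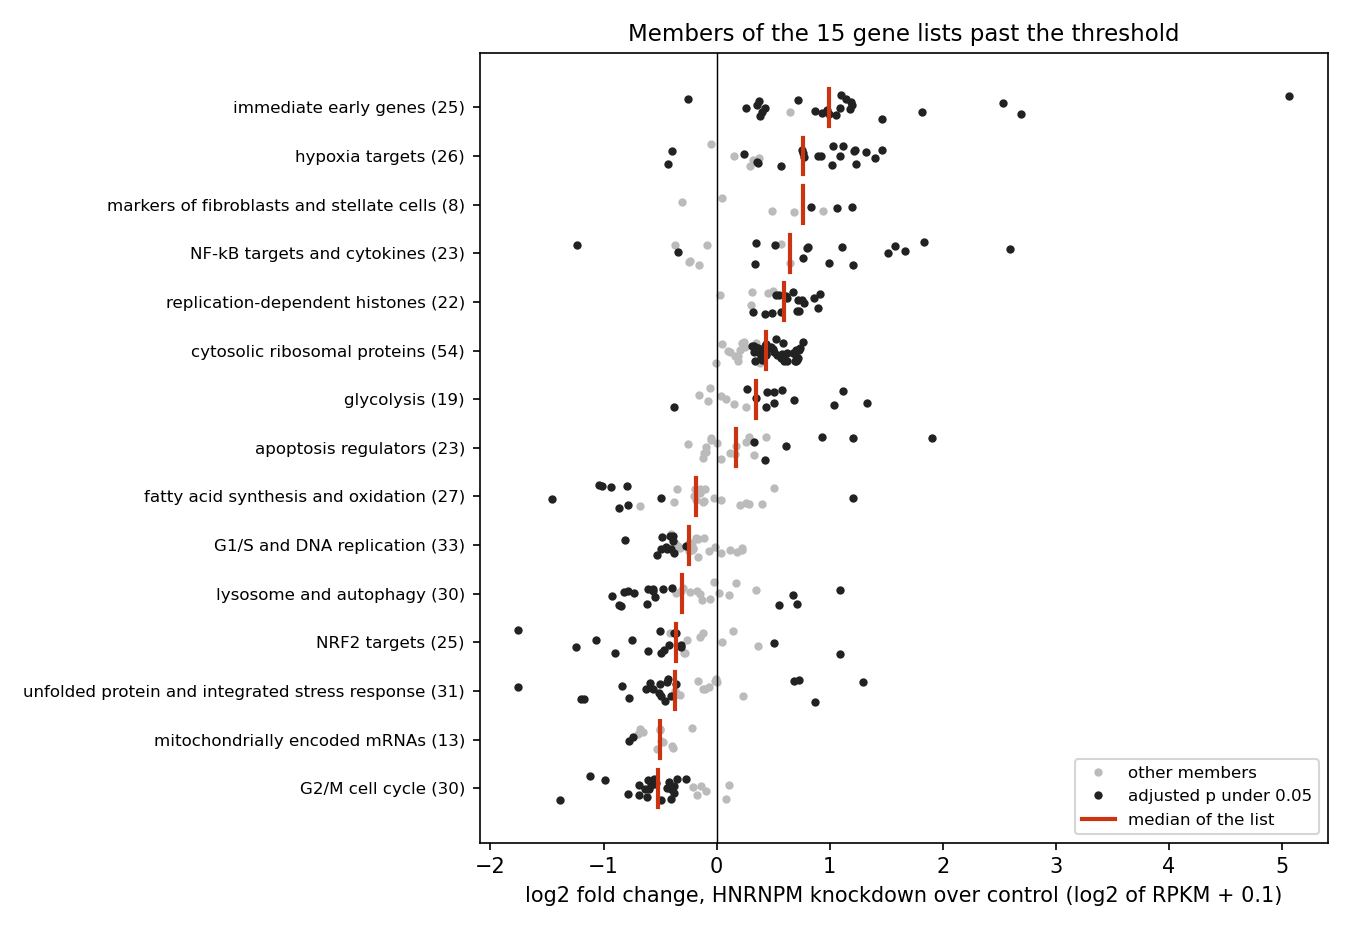
Log2 fold changes (horizontal axis, knockdown over control) of the members of the 15 lists that passed the camera test with a preset correlation, with the number of tested members in brackets. Black points passed limma's threshold, grey points did not, and red lines are list medians, which run from -0.52 in G2/M genes to 0.99 in immediate early genes.

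Apoptosis regulators had 6 of 23 members higher and 0 lower (9 and 0 adjusted over the list alone; median log2 fold change 0.17; camera adjusted p = 0.0115). The called members have opposing roles: BIK (1.91 ± 0.20) promotes cell death, whereas MCL1 (0.93 ± 0.06) and BIRC3 (1.21 ± 0.15) counteract it, though MCL1 overlaps another gene and is uncertain. Only 3 members were called without control replicate 2 or without either knockdown library. The list did not pass without control replicate 2 (camera adjusted p = 0.0609) or with an estimated correlation (adjusted p = 0.755). Among markers of cells other than hepatocytes, those of fibroblasts and stellate cells had 3 of 8 members higher and 0 lower (5 and 0 adjusted over the list alone; median 0.76; camera adjusted p = 0.0198, and 0.755 with an estimated correlation). LUM rose from 1.13 ± 0.0799 to 2.84 ± 0.208 RPKM (SD, n = 2), and the other called members, PDGFRB and COL1A1, stayed at 0.209 and 0.131 RPKM or less on average in both groups and did not pass when any 1 library was left out (adjusted p from 0.0571 to 0.136). The median of this list of genes at low levels depended on the pseudocount, with 0.14 at a pseudocount of 1 and 1.20 at 0.01, and was 0.36 with the stricter filter and 1.29 by limma-voom. The list itself did not pass without control replicate 1 (camera adjusted p = 0.0974). Immune markers had 2 of 5 members lower and 0 higher, the same adjusted over the list alone (camera adjusted p = 0.299), with CD14 at 0.784 ± 0.0786 against 0.132 ± 0.00931 RPKM. Endothelial markers had 1 of 7 higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.869; median -0.15, mean 0.06, test direction down), with LYVE1 at 0.761 ± 0.110 against 4.30 ± 0.444 RPKM. Of 5 genes of embryonic kidney cells 1 was lower and 0 when adjusted over the list alone (camera adjusted p = 0.535). With each library left out in turn, immune markers had 0 to 1 higher and 1 lower, endothelial markers 1 higher and 1 lower, and the kidney list 0 called genes.

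Lists of other splicing factors held called genes in both directions, and the counts depended on the library left out. Among all 20221 tested genes 2240 were called higher and 2792 lower. Calls in both directions are therefore not particular to these lists. Of 25 tested members of the hnRNP family other than HNRNPM, 1 was higher and 2 were lower (0 adjusted over the list alone; camera adjusted p = 0.774). Among them were HNRNPA1 (0.27 ± 0.07) and HNRNPL (-0.30 ± 0.07), and neither call held when any 1 library was left out (adjusted p from 0.0519 to 0.251). The median of the family was -0.06, and turned to 0.00174 with total-read scaling. SR proteins and other splicing regulators had 5 of 33 higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.418), with SRSF7 at 17.6 ± 0.421 against 25.0 ± 2.25 RPKM and SRSF2 at 29.6 ± 1.49 against 22.4 ± 0.878 RPKM. SRSF7 did not pass without knockdown replicate 1 (adjusted p = 0.0968) or control replicate 1 or 2 (0.0512 and 0.0636), nor SRSF2 without knockdown replicate 2 (adjusted p = 0.0577). HNRNPL and SRSF2 overlap exons of other genes and are uncertain. The core spliceosome had 2 of 37 higher and 6 lower (2 and 6 adjusted over the list alone; camera adjusted p = 0.924; median 0.05, mean -0.00261, test direction up), and nonsense-mediated decay factors had 2 of 13 higher and 3 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.869; median 0.11, mean -0.01, test direction up). UPF1, the central helicase of nonsense-mediated decay, fell from 13.3 ± 0.0392 to 8.80 ± 0.337 RPKM. The TRIM family without TRIM7 had 5 of 42 higher and 6 lower (5 and 7 adjusted over the list alone; camera adjusted p = 0.869; median -0.08, mean 0.02, test direction down), with TRIM28, a transcriptional corepressor, at 77.0 ± 2.87 against 53.1 ± 2.54 RPKM. With each library left out in turn, the hnRNP family had 0 to 1 genes higher and 0 lower, SR proteins and other regulators 0 to 1 higher and 0 to 1 lower, and the core spliceosome 1 to 3 higher and 0 to 4 lower. Decay factors had 0 to 2 higher and 1 lower, and the TRIM family 1 to 3 higher and 2 to 3 lower. The median of the core spliceosome was -0.01 without control replicate 2. Exon usage was not analysed here, since each gene has a single value.

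Lists of hepatocyte identity and of tumour phenotype held called genes in both directions. So did the tested genes at large, with 2240 higher and 2792 lower of 20221, so this alone does not set the lists apart. The hepatocyte list had 4 of 31 members higher and 8 lower (7 and 8 adjusted over the list alone; camera adjusted p = 0.869), with a median log2 fold change of 0.16, a mean of -0.03 and an upward test direction. The fibrinogen gene FGB fell with ALB and AMBP (-1.31 ± 0.13), and APOE rose from 13.0 ± 2.72 to 43.1 ± 1.13 RPKM (SD, n = 2). Xenobiotic and bile acid genes had 3 of 21 higher and 8 lower, the same adjusted over the list alone (camera adjusted p = 0.512; median -0.09, mean 0.00351, test direction down). The oncofetal and progenitor list had 6 of 24 higher and 4 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.299), and the imprinted long non-coding RNA H19 rose from 569 ± 58.7 to 1338 ± 39.3 RPKM. Mesenchymal and migration genes had 3 of 25 higher and 7 lower (4 and 8 adjusted over the list alone; camera adjusted p = 0.869), with a median of 0.08, a mean of -0.13 and a downward test direction. The mesenchymal median was -0.07 without control replicate 1 and -0.01 without knockdown replicate 1. The matrix protease MMP7 fell from 77.9 ± 6.01 to 26.7 ± 0.778 RPKM. Fibronectin, FN1, had 1694 ± 238 RPKM in control and 907 ± 59.9 RPKM in knockdown cells, a call lost without knockdown replicate 1 or 2 (adjusted p = 0.0870 and 0.0544). Collagens, laminins and matrix genes had 5 of 25 higher and 9 lower (7 and 11 adjusted over the list alone; camera adjusted p = 0.535), and among the lower ones were NID1 (-1.05 ± 0.07) and COL18A1 (-1.19 ± 0.10). Epithelial junction genes had 5 of 25 higher and 5 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.729; median 0.03, mean -0.00220, test direction up). The epithelial median was -0.08 without control replicate 1. With each library left out in turn, 2 to 6 hepatocyte genes were higher and 4 to 8 lower, 1 to 3 and 5 to 7 xenobiotic genes, and 3 to 7 and 2 to 5 oncofetal genes. Mesenchymal genes numbered 0 to 3 higher and 3 to 8 lower, matrix genes 1 to 3 and 6 to 9, and epithelial genes 1 to 4 and 1 to 3. APOE, H19 and COL18A1 overlap exons of other genes and are uncertain.

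Signalling lists that did not pass the test also held genes with large changes. Their counts stand beside 2240 genes called higher and 2792 called lower among all 20221 tested, so called members alone do not set these lists apart. The growth factor receptors FGFR3, FGFR4 and ERBB3 had log2 fold changes of -1.44 ± 0.11, -1.37 ± 0.11 and -1.27 ± 0.13 in the list of receptor tyrosine kinase and MAPK output, where 5 of 24 genes were higher and 8 lower (5 and 9 adjusted over the list alone; camera adjusted p = 0.517). Wnt/beta-catenin targets had 3 of 18 higher and 6 lower (5 and 7 adjusted over the list alone; camera adjusted p = 0.869), with DKK1, a secreted Wnt antagonist, at 43.9 ± 5.13 against 18.9 ± 1.95 RPKM (SD, n = 2). TGF-beta targets had 4 of 20 higher and 7 lower (5 and 8 adjusted over the list alone; camera adjusted p = 0.535), with BAMBI at 45.9 ± 0.876 against 21.7 ± 1.57 RPKM. YAP/TEAD targets had 4 of 18 higher and 4 lower (7 and 4 adjusted over the list alone; camera adjusted p = 0.278). The p53 targets had 3 of 26 higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.535; median -0.01, mean 0.07, test direction up), with BTG2 at 0.98 ± 0.12. Interferon-stimulated genes had 9 of 44 higher and 5 lower (9 and 8 adjusted over the list alone; camera adjusted p = 0.512), with BST2 at 1.39 ± 0.17 and TAP1 at -1.04 ± 0.12. Heat shock and chaperone genes had 4 of 18 higher and 1 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.512). Cholesterol synthesis had 3 of 24 higher and 6 lower (4 and 8 adjusted over the list alone; camera adjusted p = 0.982; median 0.02, mean -0.04, test direction up). The nuclear-encoded respiratory chain had 3 of 32 higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.869; median 0.01, mean -0.04, test direction down). Among non-coding RNAs, 3 of 17 snoRNA host genes were higher and 5 lower (4 and 5 adjusted over the list alone; camera adjusted p = 0.774). The abundant structural RNAs had 1 of 23 higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.233), and the nuclear long non-coding RNAs 5 of 14 higher and 2 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.153). TERC, the telomerase RNA, had a log2 fold change of -1.17, and like TAP1 and ERBB3 it overlaps the exons of another gene and is uncertain. With each library left out in turn, 5 receptor and MAPK genes were higher and 5 to 6 lower, 2 to 3 and 4 to 5 Wnt targets, 1 to 2 and 4 to 6 TGF-beta targets, 2 to 4 and 2 to 3 YAP targets, and 2 to 4 and 0 to 1 p53 targets. Interferon-stimulated genes numbered 5 to 7 higher and 2 to 5 lower, heat shock genes 2 to 4 and 0 to 1, cholesterol genes 0 to 1 and 3 to 5, and respiratory chain genes 0 to 3 and 1 to 3. Among non-coding RNAs the numbers were 0 to 1 and 2 to 4 for snoRNA hosts, 0 to 1 and 3 to 6 for structural RNAs, and 2 to 3 and 0 for long non-coding RNAs. No list in these last comparisons passed with an estimated correlation or by fry. The medians of the p53, Wnt, TGF-beta and snoRNA host lists lay within 0.05 of 0 and changed sign with total-read scaling (0.05, 0.05, 0.03 and 0.02), the p53 and Wnt lists also with median-of-ratios scaling (0.01 for both). Medians also changed sign without control replicate 1 for interferon-stimulated genes (-0.02), without control replicate 2 for the p53, Wnt, TGF-beta and respiratory lists (0.02, 0.02, 0.03 and -0.06), without knockdown replicate 1 for the p53, Wnt and respiratory lists (0.07, 0.01 and -0.05), and without knockdown replicate 2 for the respiratory list (-0.01).

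Tested by chromosome, 1 of 24 sets of genes stood apart, the mitochondrial genome (37 genes, mean log2 fold change -0.38, camera adjusted p = 0.000135). That call was lost without knockdown replicate 1 (adjusted p = 0.0847) and with an estimated correlation (adjusted p = 0.944). The count for nuclear chromosomes was 0 at this threshold and also 0 at an unadjusted p under 0.05, with mean log2 fold changes from -0.08 to 0.04.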

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

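The pseudocounts of 1 and 0.01, thinning, removal of the length trend and robust moderation were chosen after seeing the data. The planned count-model fits were not run, although the recovered reads would have allowed them. HNRNPM was lower and past the threshold under all alternatives run, with log2 fold changes from -1.39 to -1.28. TRIM7 never passed, and its estimate turned to -0.17 without knockdown replicate 2, its lowest value with 1 library left out, against 0.22 without knockdown replicate 1. The count of 5032 genes moved to 1806 with no filter (693 higher, 1113 lower), to 1395 at an adjusted p under 0.01 (575 higher, 820 lower) and to 862 with a log2 change of at least 1 (460 higher, 402 lower). With limma-voom it was 7232 (3278 higher, 3954 lower). Leaving out 1 library gave 2513 (without knockdown replicate 1) to 3218 genes (without control replicate 1), with 968 to 1531 higher and 1322 to 1690 lower, as fewer samples leave less power. The gene count lay between 4362 and 5446 under the other alternatives. With a replicate block the count was 5129, of which 4613 were shared. Same-numbered libraries deviated together across genes with a correlation of only 0.06, so any effect they shared was small next to other differences. Whether they shared a culture or day is not given by the labels and stays open.

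Of the 15 called lists, 13 to 15 passed under the scalings, filters, pseudocounts, thinning, length correction, replicate block and left-out libraries, 0 with an estimated correlation and 4 with fry. The count of 13 came from scaling without mitochondrial, histone and structural RNA genes, which left mitochondrial mRNAs and histones untested, not lost. With the stricter filter fibroblast markers had 4 tested members, under the minimum of 5. The test with an estimated correlation had only 2 residual degrees of freedom, so its count of 0 says little about single lists. Counts within lists depended more on the setting: with no filter 15 immediate early, 13 hypoxia, 5 glycolysis, 7 NF-kB, 8 ribosomal protein and 5 histone genes were called higher, and 16 G2/M, 5 G1/S, 8 stress response, 5 NRF2 and 6 lysosome genes lower. Fibroblast markers were lost with no filter, with a pseudocount of 1, after thinning and without control replicate 1, apoptosis regulators without control replicate 2, and mitochondrial mRNAs without knockdown replicate 1. The chromosome call went from 1 to 0 when mitochondrial genes were removed, which leaves that set untested, and to 0 with an estimated correlation; with libraries left out it was 0 to 1. Of 177 named-gene results besides HNRNPM and TRIM7, 0 changed direction, 46 lost or lacked their call with no filter, and 21, 28, 35 and 35 did so without control replicate 1, control replicate 2, knockdown replicate 1 and knockdown replicate 2. The knockdown libraries are shallower than the controls, which limits what is known of genes at low levels.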

Other observations

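The tests of the length trend, of a single deviating library, of heat shock, of handling, of all mitochondrial transcripts, of lists matched on length and of liver X receptor targets were chosen only after the result was seen. The gene groups of 3 patterns were weighed against technical explanations, and both receptor hypotheses arose from changes already seen, with their targets named here after their values were seen.

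ABCA1 and further targets of the liver X receptors were picked after values were seen. ABCA1, a cholesterol exporter, fell from 14.8 to 5.63 RPKM (log2 fold change -1.43 ± 0.13, limma adjusted p = 0.00430), ABCG1 by 3.03 and SREBF1 by 1.45 on the log2 scale. All 3 are targets of the liver X receptors, so lower activity of these receptors may connect them. The median log2 fold change of 7 other tested targets was -0.77, with 4 lower and 1 higher: PLTP (-0.90), LPCAT3 (-0.82), SCD (-1.04) and MYLIP (-0.77) fell. MYLIP did not pass without control replicate 1 or 2 or knockdown replicate 1 (adjusted p = 0.0776, 0.108 and 0.0789). APOE, also a target, rose by 1.68, which goes against the hypothesis, and PLTP overlaps CTSA. No receptor activity was measured.

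CYP1A1 had the second largest increase among named genes and is a classical target of the aryl hydrocarbon receptor. The median of 6 other tested targets was 0.12, between the values set for and against such an activity. TIPARP (0.97) and CYP1B1 (0.51) rose and UGT1A6, which shares exons with other UGT1A genes, fell by 0.85 on the log2 scale. CYP1B1 did not pass without knockdown replicate 1 (adjusted p = 0.0613). CYP1A1 was thus not the only target to rise, but the called targets moved in both directions, so whether the receptor was involved stays open.

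Of 54 ribosomal protein genes 41 were called higher, but only 11 and 15 without knockdown replicate 1 and 2. After the length trend was removed their median log2 fold change was 0.46, and 0 of 10000 random lists matched on length and expression reached the observed median. This argues against annotated exon length as the whole cause. The trend of median fold changes with that length was small to begin with, although the direction of calls shifted with it. A bias tied to the length of the mRNAs themselves was not tested. The 145 tested ribosomal protein pseudogenes had a median of 0.46, with 47 higher and 2 lower. They did not fall as their parents rose, which argues against a move of reads from pseudogenes to parents as the whole cause. Pseudogenes can hold reads of their parents and rise with them, so a partial move is not excluded. With all libraries thinned to equal depth the median of the ribosomal protein genes was 0.46. Thinning hardly changes the ratio of genes with many reads, such as RPS15 with 3183 to 3543 per library. This test could therefore hardly have come out otherwise, and no conclusion is drawn from it. A response to HNRNPM loss stays a hypothesis, since delivery of a hairpin is confounded with the group.

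Immediate early genes were higher by a median of 0.97 in the knockdown library with the lower value, so no single library carries the pattern. The heat shock and chaperone list had a median of 0.0346 with members called in both directions, 4 higher and 1 lower. CRYAB (1.54), HSPA6 (1.06) and DNAJB1 (0.51) were among the higher ones, HSPA6 not without control replicate 2 or knockdown replicate 2 (adjusted p = 0.0698 and 0.0536), and CRYAB and DNAJB1 overlap other genes. CRYAB and HSPA6 stayed at 1.53 and 1.08 RPKM or less on average in both groups. The lower member was HSPH1 (-0.39 ± 0.07), at 11.4 RPKM in control and 9.07 RPKM in knockdown cells. A heat shock response therefore stays open. A difference in harvest or handling between the cultures cannot be told apart from the knockdown: the median absolute difference between libraries of 1 group was at most 0.0877, but libraries of a group could have been handled together.

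Mitochondrial ribosomal RNAs were higher while mitochondrial mRNAs had a median of -0.50, which does not exclude a fall of all mitochondrial transcripts if depletion of mitochondrial ribosomal RNA differed. Less complete depletion of ribosomal RNA would raise cytosolic ribosomal RNA too, but the summed rows were lower (log2 ratio -0.61, from 3326 to 9164 reads per library). This rests almost wholly on the 5.8S gene, which gave 97.3% to 98.6% of those reads, so the other cytosolic ribosomal RNAs were hardly measured. Less complete depletion, in general or of mitochondrial ribosomal RNA alone, remains open, as does a response to the knockdown.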
